A study of Drosophila melanogaster with 4 samples.

How the data were processed

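Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 mono-methylated at lysine 9 (H3K9me1) in nuclei of wild-type Oregon-R Drosophila melanogaster larvae of the third instar. The series holds 4 samples, 2 ChIP replicates made with antibody lot 2 and 2 input replicates of unprecipitated chromatin. Samples were grouped by their titles, and the replicate numbers come from the same titles. Per the labels, input replicate 1 served as the background of ChIP replicate 1 and input replicate 2 as that of ChIP replicate 2. Nothing in the labels says whether the replicates came from separate larval collections, so the spread between them may be technical in part.

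Per the labels' protocols, larval tissue was crosslinked with formaldehyde, chromatin was sheared by sonication, and antibody-bound fragments were collected on beads. The submitters' processing notes name Bowtie 0.12.7, a short-read aligner. Per the file headers, coordinates are on FlyBase release 5. The software that called the regions, its thresholds and its filters are not given in the sources used here, and neither is read depth. The authors deposited 3 region lists, 1 per ChIP replicate and 1 combined list for both. Each region carries a score that the authors deposited with it, above 0 in regions listed as enriched and below 0 in regions listed as depleted. The scale of the score is not given in the sources used here, so the comparisons of the report used it only to rank, filter or describe regions within a list. Some checks of explanations also set score differences of the 2 replicate lists side by side, which assumes a shared scale, and nothing was decided from them. Region length, number and position depend on the upstream calls, and a shallower library can lose weak regions or break long ones into pieces. How the combined list was made is not given in the sources used here. Because it rests on the same samples as the replicate lists, the overlap of its domains with theirs was not tested.

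Enriched regions are called domains here. Regions listed as depleted were kept apart. Sequence lengths were read from the file headers. The covered share of a sequence is the number of its bases inside domains divided by its length. Means and SDs are over the 2 ChIP replicates. The large arms are 2L, 2R, 3L, 3R and X, and the Het scaffolds are 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet.

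Overlaps of domains were counted with bedtools 2.31.1, at 1 bp or more. Overlap of covered bases was summarised by the Jaccard index (shared bases over bases in either list) and tested one-sided against circular shifts of replicate 2 within each sequence, with 100000 draws on bins of 100 bp. Coverage was compared between X and the autosomal arms in windows of 100 kb, by a two-sided permutation test with 100000 resamples. Neighbouring windows are not independent, so rotations of the X block along the joined arms were added, which take this into account only in part. The 2 Mb next to the centromere were compared with the rest of each large arm by an exact two-sided sign-flip permutation test over the 5 arms. Scores of domains found in the other replicate and of those not found were compared by a two-sided permutation test of medians with 100000 resamples. P-values given as adjusted were adjusted by the Benjamini-Hochberg method within each family of tests, and the others were not adjusted. Scripts ran under Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

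The main tests and the rule for named regions were fixed before the data were examined, as were the alternatives except those named as chosen later. Overlap tests of single sequences, window correlations, and the X tests of single replicates, of their difference and by rotation were added after seeing the data. The rule took the 10 highest-scoring and the 10 longest domains of the combined list, among those with at least 50% of their length inside domains of each replicate, and the longest such domain on each large arm and on chromosome 4. Planned tests on gene features and on 12 gene lists were not run, because the gene table at hand is on release 6 of the genome and coordinates were not converted between builds. No gene is therefore named. The circular-shift test was tried on simulated lists with the domain lengths of the real replicates, placed at random and without their clustering. With independent lists, 4 of 100 simulations passed a threshold of 0.05 in the circular-shift test. For the window test, the windows of replicate 1 were shuffled, which removes the dependence of neighbouring windows. With X raised by 5 percentage points, the window test then passed in 82 of 100 simulations, and with no difference in 5 of 100. These rates hold for independent windows and do not show how the test behaves on the real, dependent ones. Alternatives covered the overlap criterion, a stricter score threshold, minimum lengths, merging of domains within 1000 bp, the window size, the extent of the proximal part, the combined list and leaving out each replicate.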

Results

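H3K9me1 domains were mapped in larval nuclei in 2 ChIP replicates, each called against its own input. The list of replicate 1 held 8304 domains that covered 37.2 Mb, and the list of replicate 2 held 11820 domains that covered 36.8 Mb. The combined list held 13702 domains over 50.0 Mb. Domains had a median length of 2.42 kb in replicate 1 and 2.18 kb in replicate 2, and the shortest measured 1301 bp in both. Replicate 1 held 781 domains of 10 kb or more, which made up 38.1% of its covered bases, and replicate 2 held 300, which made up 11.1%. The longest domain measured 83.1 kb in replicate 1 and 42.0 kb in replicate 2. The read depth of the libraries is not given in the sources used here, so the values below carry no counting error and their spread is that between the 2 replicates.

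**Figure D1:**
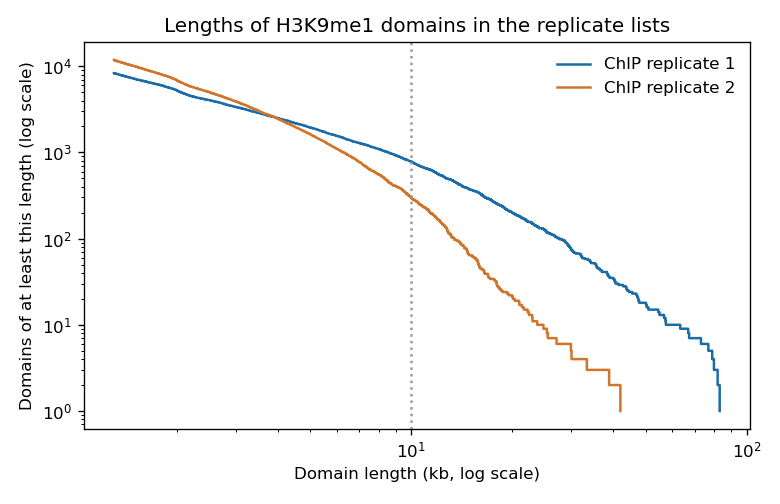
Number of H3K9me1 domains (vertical axis, log scale) at least as long as the length on the horizontal axis (kb, log scale) in each ChIP replicate, with a dotted line at 10 kb. Replicate 2 has more domains in all, 11820 against 8304, and fewer of 10 kb or more, 300 against 781.

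The first comparison asked how far the replicates mark the same sequence. Replicate 1 and replicate 2 shared 21.8 Mb, which was 58.6% of the bases covered in replicate 1 and 59.3% of those in replicate 2. Of the domains of replicate 1, 5640 (67.9%) overlapped a domain of replicate 2, and of the domains of replicate 2, 7330 (62.0%) overlapped one of replicate 1. Of the 781 domains of 10 kb or more in replicate 1, 739 were found in replicate 2, and of the 300 in replicate 2, 277 were found in replicate 1; at a minimum of 1 bp, length alone raises such shares. The Jaccard index was 0.418, against a mean of 0.181 and a maximum of 0.249 over circular shifts (one-sided permutation test, p = 1e-05, the smallest that the draws can give). The shared bases were 1.92 times the mean of the shifts.

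The overlap held on each arm. The Jaccard index was 0.460 on 2R, 0.436 on 3R, 0.430 on 3L, 0.388 on 2L and 0.385 on X, and each exceeded circular shifts of that arm (one-sided permutation test, adjusted p = 2.7e-05). On chromosome 4, the small and largely heterochromatic dot chromosome, it was 0.168 (one-sided permutation test, adjusted p = 1e-04). There, 12 of the 19 domains of replicate 1 were found in replicate 2, and 12 of the 59 of replicate 2 in replicate 1. On the Het scaffolds, assembled heterochromatic sequence, 1 of the 14 domains of replicate 1 was found among the 55 of replicate 2. The index there, 0.010, did not exceed circular shifts (one-sided permutation test, adjusted p = 0.31). Across windows of 100 kb, which are not independent replicates, covered shares of the replicates correlated with a Pearson r of 0.62 on X, 0.65 on 2L, 0.68 on 2R, 0.71 on 3L and 0.74 on 3R. Spearman's rho ran in the same order of arms 0.62, 0.69, 0.70, 0.69 and 0.73. The permutation test over all rotations within an arm gave an adjusted p of 0.0047 for each of these 10 coefficients, and no rotation reached the observed value.

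The combined list was set beside the replicate lists to see which of its domains rest on both. Of its 13702 domains, 5177 (37.8%) overlapped domains of both replicates, and these held 66.7% of its covered bases. They had a median length of 4378 bp. A further 2906 domains (21.2%) overlapped replicate 1 alone, with a median length of 1812.5 bp, and 3938 (28.7%) overlapped replicate 2 alone, with a median length of 1690.5 bp. The remaining 1681 domains (12.3%) overlapped neither replicate and had a median length of 1193 bp. The combined list reaches down to 1001 bp, while the replicate lists hold no domain under 1301 bp, so their length floors differ. With a minimum of 2000 bp in all lists, 6.21% of the combined domains overlapped neither replicate. The combined list is made of the same samples, so these shares are a description and not a test.

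Coverage by sequence shows where on the genome the mark was called. H3K9me1 domains lay on the euchromatic arms and were sparse on chromosome 4 and on the Het scaffolds. The 5 large arms together were covered to 30.9% ± 0.38 (SD, n = 2). By arm, the covered share was 34.1% ± 1.67 on 2R, 31.2% ± 3.83 on 3L, 29.6% ± 2.45 on 3R and 26.5% ± 2.22 on 2L (SD, n = 2). On X it was 33.8% ± 9.09 (SD, n = 2), the widest spread among the large arms. Chromosome 4 was covered to 6.14% ± 4.56 (SD, n = 2), with 19 domains in replicate 1 and 59 in replicate 2. The ratio of chromosome 4 to the large arms was 0.093 in replicate 1 and 0.305 in replicate 2, and in both it lay below the least covered large arm. The Het scaffolds, 9.28 Mb in all, were covered to 0.271% in replicate 1 and 1.08% in replicate 2, a ratio to the large arms of 0.0087 and 0.035. XHet stood apart among them in replicate 2, at 17.4% against 1.66% in replicate 1. The unplaced scaffold U, of 10.0 Mb, held 2 domains in replicate 1 and 23 in replicate 2, and Uextra held none in any of the 3 lists. The coverage of chromosome 4 and of the scaffolds was not tested against that of the large arms, because chromosome 4 is a single sequence and the share of the scaffolds to which reads can be placed is unknown.

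**Figure D2:**
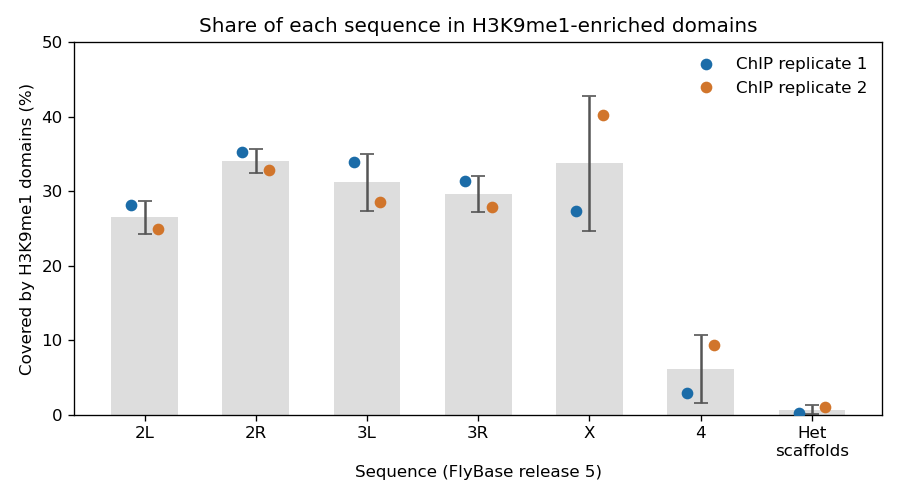
Percent of each sequence covered by H3K9me1 domains (vertical axis) for the large arms, chromosome 4 and the pooled Het scaffolds (horizontal axis); points are the 2 ChIP replicates, bars their mean and error bars the SD. The autosomal arms reach from 26.5% on 2L to 34.1% on 2R in the mean, chromosome 4 at 2.91% and 9.36%, and X at 27.3% in replicate 1 and 40.2% in replicate 2.

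X was then compared with the autosomal arms, and the difference changed sign between the replicates. In replicate 1, X at 27.3% lay close to the lowest autosomal arm, 2L at 28.1%, and 2R reached 35.2%. In replicate 2, X at 40.2% lay above the highest autosomal arm, 2R at 32.9%. In replicate 1, X was covered less than the autosomal arms, 27.3% of a 100 kb window on average against 32.1%, a difference of -4.79 percentage points (two-sided permutation test over windows, adjusted p = 0.0089). In replicate 2, X was covered more, 40.2% against 28.5%, a difference of 11.7 points (two-sided permutation test over windows, adjusted p = 2.5e-05). Replicate 2 minus replicate 1 was 12.9 points on X, against -3.15 on 2L, -2.36 on 2R, -5.41 on 3L and -3.46 on 3R; on chromosome 4 it was 6.45 points, in the same direction as X. This difference between replicates was 16.5 points larger on X than on the autosomal arms (two-sided permutation test, adjusted p = 2.5e-05). In the mean of both replicates X exceeded the autosomal arms by 3.46 points (two-sided permutation test, adjusted p = 0.022). Windows are neighbours and not independent replicates. When the X block was rotated along the joined arms, the unadjusted p (permutation test over rotations) was 0.40 for the mean and 0.30 for replicate 1. It was 0.029 for replicate 2 and 0.0034 for the difference between replicates. Adjacent rotations share most of their windows, so these p-values are a rough guide only.

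The ends of the arms next to the centromere were compared with the rest of each arm. Coverage was lower in the proximal 2 Mb of 4 of the 5 large arms. It was 7.65% against 36.9% on 2R, 7.16% against 33.4% on 3L, 15.0% against 27.6% on 2L and 16.3% against 35.5% on X, as means of both replicates. On 3R it was 37.1% in the proximal 2 Mb against 29.1% in the rest. The difference over the 5 arms was -15.9 ± 14.8 percentage points (SD over n = 5 arms; exact sign-flip permutation test, p = 0.12), and 5 arms cannot give a p below 0.0625. Narrower stretches were picked after the profiles were seen. The first 1.5 Mb of 2R were covered to 0.84% in replicate 1 and 3.05% in replicate 2, and 3L from 23 Mb to its end to 0.22% and 1.48%. The first 0.5 Mb of 3R, in contrast, were covered to 30.0% and 41.7%. The share of these proximal ends to which reads can be placed is unknown, as on the scaffolds. Low coverage there need not mean low H3K9me1, and the same holds for the contrast with 3R.

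**Figure D3:**
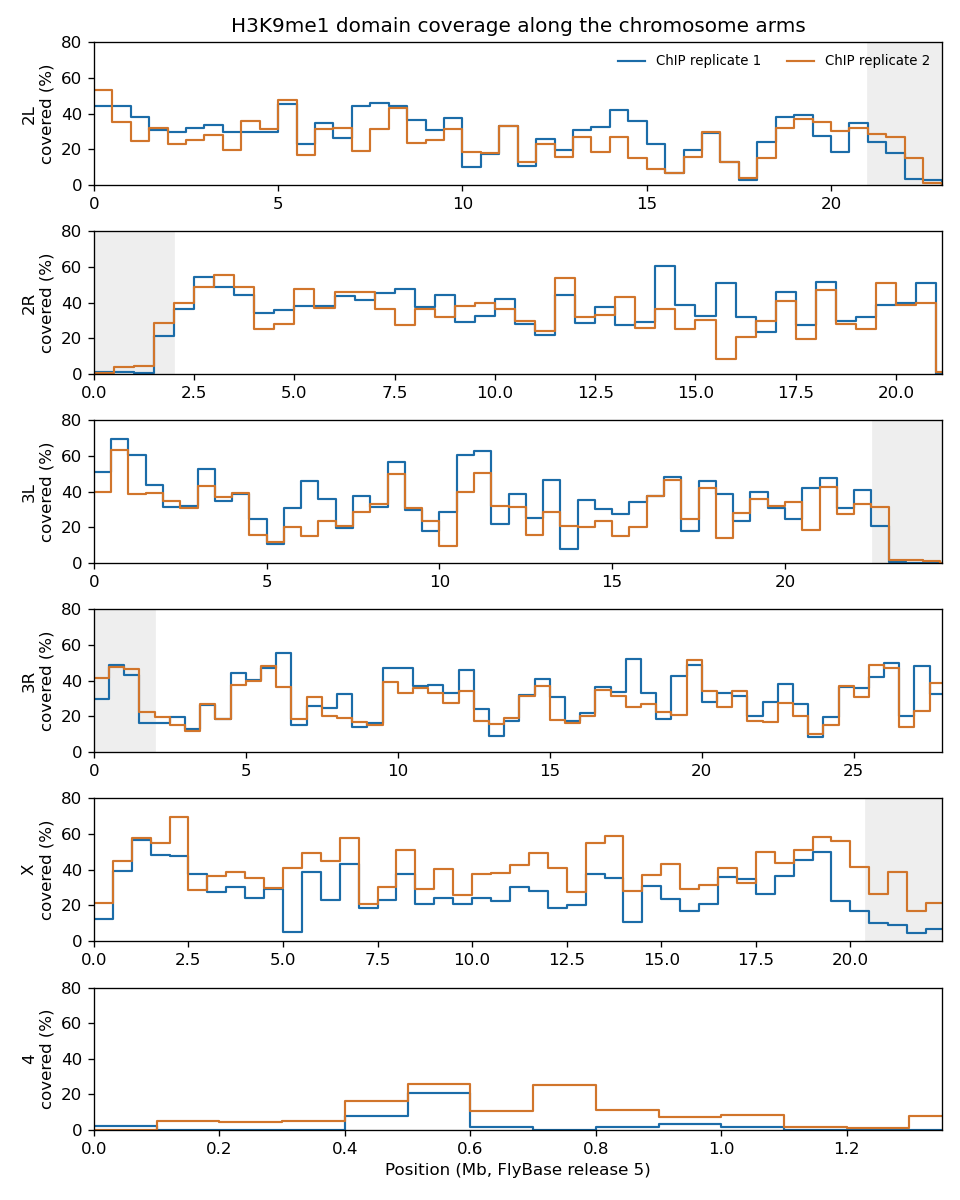
Percent of sequence covered by H3K9me1 domains (vertical axes) along the large arms in bins of 500 kb and along chromosome 4 in bins of 100 kb (horizontal axes, Mb, FlyBase release 5) in each ChIP replicate; grey marks the 2 Mb next to the centromere. Coverage drops in the proximal parts of 2L, 2R, 3L and X and not on 3R, and the line of replicate 2 runs above that of replicate 1 over most of X.

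The fixed rule named 20 regions of the combined list, 7 on 3L, 4 on X, 3 each on 2R and 3R, 2 on 2L and 1 on chromosome 4. Positions are on release 5, and genes under them were not analysed here. The longest lay on X from 1441268 to 1523003, spanned 81.7 kb with an authors' score of 1.67, and had 99.2% of its length in domains of replicate 1 and 93.1% in those of replicate 2. The longest on 2R ran from 6914844 to 6994486 (79.6 kb), that on 3R from 10228071 to 10307249 (79.2 kb), that on 3L from 8809409 to 8882782 (73.4 kb) and that on 2L from 494952 to 539867 (44.9 kb). The longest on chromosome 4, from 525227 to 529694, measured 4.47 kb. Among the 10 longest, 5 lay on 3L, 3 on 3R and 1 each on 2R and X, and the shortest of them measured 54.9 kb. A pair of the long regions on 3L were neighbours, from 712343 to 769691 and from 770077 to 826866. Over the 10 longest regions, replicate 1 listed 13 domains and replicate 2 listed 100. The longest domain of replicate 2 measures 42.0 kb, so choosing the longest regions favours several of its domains in each. These counts are a description only.

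The highest-scoring named region lay on 3R from 12030976 to 12085894, with an authors' score of 1.70 in the combined list; its best domain ranked 4 by score within replicate 1 and 8 within replicate 2. It was followed by a region of 11.9 kb on 3L from 22826247 to 22838115, within the proximal 2 Mb of that arm, whose best domain ranked 5 within replicate 1 and 276 within replicate 2. Of the 10 highest-scoring regions, 4 lay on X, 2 each on 2R and 3L, and 1 each on 2L and 3R. The region on X and the one on 3R from 12030976 were among both the longest and the highest-scoring. All 20 regions had at least 67.8% of their length inside domains of either replicate taken alone.

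Scores were compared within each list between domains found in the other replicate and domains not found. Shared domains scored higher in both lists. In replicate 1 the median score was 0.658 for the 5640 shared domains and 0.500 for the other 2664, a difference of 0.158. In replicate 2 it was 0.601 for 7330 shared domains and 0.537 for the other 4490, a difference of 0.064 (two-sided permutation test in each list, adjusted p = 1e-05, the smallest that the resamples can give). In the top 10% of scores 96.6% of the domains of replicate 1 and 82.1% of those of replicate 2 were shared, against 48.4% and 53.3% in the bottom 10%. Shared domains were also longer, and within 3 classes of domain length the difference was 0.091 in replicate 1 and 0.0074 in replicate 2. Neither comparison was made within chromosomes, and neighbouring domains are not independent, which these p-values ignore. Median scores on X and on the autosomal arms were 0.645 and 0.574 in replicate 1, and 0.657 and 0.548 in replicate 2. Of the X domains, 80.5% were shared in replicate 1 and 50.5% in replicate 2. How far X moves the score differences was not tested.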

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

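The tests on depleted regions were chosen after the lists were seen. Besides domains, the lists hold regions marked as depleted of H3K9me1, which enter no comparison above: 11 in replicate 1, 2 in replicate 2 and 49 in the combined list. They were taken up because they number more than 3 in replicate 1 and in the combined list. That limit is not the number of such calls expected by error, which is unknown. They are short, from 1265 to 1758 bp in the combined list, and none of the 49 overlaps a depleted region of either replicate. None of the 11 in replicate 1 overlaps one of replicate 2 either. Of the 49, 44 (89.8%) overlap a domain called enriched in a replicate, against a mean of 51.8% and a central 95% range of 38.8% to 65.3% over 10000 circular shifts, so a random placement with respect to the domains of both replicates together is argued against, although the lists rest on the same samples and are not independent. Taken alone, the domains of replicate 1 are overlapped by 55.1% of the 49 (shifted range 24.5% to 51.0%) and those of replicate 2 by 46.9%, which lies within its shifted range (26.5% to 53.1%). A total of 38 lie over a domain of exactly 1 replicate, 6 over domains of both and 5 over neither. No biological explanation was tested.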

How the results depend on the processing

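Of 143 alternative values for 21 results, 43 had an outcome fixed in advance, and of the other 100, 64 were counted as unchanged. They kept their direction and side of the threshold, or moved by less than the SD over the replicates or the interval of the share. The count of 64 overstates robustness, because some of these values were free to change only in part. The proximal difference could change its direction only, since 5 arms cannot give a p below 0.0625. Removing domains can only lower a covered share. For chromosome 4 the SD was 4.56 on a mean of 6.14%, so 2.00% at or above the median score counted as unchanged. The tests with a minimum of 2000 bp, with rotation of the X block, on arms without their proximal 2 Mb (for the Jaccard index) and without 3R were chosen after seeing the data. The minimum of 1000 bp removed no domain and tests nothing. The Jaccard index stayed between 0.356 and 0.427, above circular shifts in each alternative. The share of replicate 1 domains found in replicate 2 (67.9%) was 55.4% with at least 50% of the domain covered, 36.0% with reciprocal overlap of 50%, 60.5% at or above the median score, 71.4% after merging and 61.7% from 2000 bp. The share of replicate 2 domains found in replicate 1 (62.0%) was 54.7%, 25.3% and 55.7% under the first 3 of these. The share of combined domains found in both (37.8%) was 29.3% with at least 50% covered, 35.3% at or above the median score and 43.0% from 2000 bp. Coverage of the large arms (30.9%) was 41.8% in the combined list, 22.7% at or above the median score, 32.0% after merging and 25.7% from 2000 bp; removing domains lowers and joining them raises this value by construction, and the cause of the higher value in the combined list was not tested. X against the autosomal arms reversed with replicate 1 alone: the range over leaving out a replicate was -4.79 to 11.7 points, so replicate 2 decides the direction of the mean. It stayed positive but lost its call from 2000 bp (2.51 points, p = 0.068, permutation test) and under rotation of the X block (3.46 points, p = 0.40), where the cause was not tested beyond the dependence of neighbouring windows. The ratio of chromosome 4 to the large arms ran from 0.093 to 0.305 and that of the Het scaffolds from 0.0087 to 0.035 over the replicates. The proximal difference was negative in each alternative, from -10.6 points for the proximal 3 Mb to -22.2 in the combined list, with -11.7 to -20.0 over the replicates; leaving out 3R, the one arm with a positive difference, can only lower it and tests nothing. The score difference in replicate 2 fell from 0.064 to 0.0074 within 3 classes of length (p = 0.039, permutation test), without a split by chromosome. No paired analysis was possible because the input samples have no region list of their own here, so ChIP and input of one replicate number could not be set against each other. The tests on gene features and gene lists, and their alternatives, were not run because no annotation on release 5 was used here. Depth is unknown, so what it limits could not be measured.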

Other observations

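The tests on X windows, score percentiles, short-domain scores, domains listed on chromosome 4 and the scaffolds, domains of 10 kb or more and distal ends were chosen after these or closely related values were seen, and only the test of merging was not. The distal ends of 3L and 2L were covered more than the middle of those arms. The distal 1 Mb was covered to 56.0% on 3L against 32.4% in the middle of the arm, and to 44.3% against 26.8% on 2L, as means of both replicates. The values were 37.4% against 36.9% on 2R, 32.5% against 28.9% on 3R, and on X 29.5% against 35.8%. The hypothesis that distal ends are covered more was met by 4 of the 5 arms in the mean (mean difference 7.78 points, exact sign-flip permutation test, p = 0.31), by 4 in replicate 1 and by 3 in replicate 2, which leaves it undecided. On chromosome 4 the bin from 500001 to 600000 held the highest coverage in both replicates, 20.9% and 25.8%.

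X lay below the autosomal arms in replicate 1 and above them in replicate 2. A gain in a few regions of X is argued against: 79.0% of the X windows had more coverage in replicate 2, against 46.5% of the autosomal windows, a gap of 32.5 points. An offset of the ChIP to input ratio along the whole X in one replicate stays open: X domains found in both replicates stood 8.65 percentiles higher among the large-arm scores of replicate 2 than among those of replicate 1, but they are 1252 of 1556 X domains in replicate 1 and 1426 of 2823 in replicate 2, so this comparison decides nothing. A lower read depth on X in replicate 1 is open too: short X domains scored above short autosomal ones by 0.076 in replicate 1 and 0.086 in replicate 2, and the difference of -0.0093, which assumes a shared scale, has an interval that spans 0 (-0.025 to 0.0092). The make-up of the larvae, such as their sex, is not given by the labels and was not tested, and which library of a pair carries an offset is open.

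Domains were few on chromosome 4 and the Het scaffolds. These sequences were not left out of the calling, since the shorter count of domains on them is 33, in replicate 1, and 114 are listed in replicate 2. A lower depth on chromosome 4 stays open: its short domains differed in median score from those of the large arms by -0.069 in the mean of both lists (95% bootstrap interval -0.126 to -0.0035), against the direction that a lower depth would give, and by -0.039 in replicate 2 (-0.100 to -0.0098), but the lists need not share a scale and in replicate 1 the interval spans 0 (-0.183 to 0.027). For the Het scaffolds the same mean was -0.0043, with -0.028 in replicate 1 and 0.019 in replicate 2 and intervals that span 0 in both, so a lower depth there stays open too. No biological explanation was tested, as the design has no group that bears on it.

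Replicate 1 listed fewer and longer domains than replicate 2. Splitting of replicate 2 at short gaps as the whole cause is argued against, since merging domains within 1000 bp left 1.49 times as many in replicate 2, against 1.42 times before, and the ratio was 1.49 within 2000 bp and 1.39 within 5000 bp. The mere addition of short domains would leave the number of long ones unchanged. Replicate 2 had 0.384 times as many domains of 10 kb or more (95% exact interval 0.335 to 0.439, counting error only). These are the counts that raised the question, so this restates the pattern and is not a separate test. What stays open is a mixture of splitting and addition. By 1 bp or more, 602 of the 781 long domains of replicate 1 overlapped 2 or more domains of replicate 2. Of the 300 long domains of replicate 2, 78 overlapped 2 or more of replicate 1. The larger number of domains in replicate 2 and the longer ones in replicate 1 both raise the first count. No baseline was computed, so these counts do not decide it. No biological explanation was tested.

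The 7 highest scores of the combined list belong to domains of 1.00 to 1.87 kb, and 6 of these overlap no domain of either replicate; the highest, 2.89, is on X from 12277247 to 12278256. These were singled out after their values were seen. All but the longest of them are shorter than 1301 bp, the shortest domain in either replicate list. In replicate 2 the 6 highest scores, in domains of 1.40 to 3.03 kb, overlap no domain of replicate 1, and the highest, 3.66, is on the unplaced scaffold U from 5376989 to 5378434.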
